A study of Homo sapiens with 6 samples.

How the data were processed

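Total RNA of 6 ARPE-19 cultures, 3 untreated (vehicle) and 3 treated with 250 µM FAC for 2 days, was amplified, biotin labelled and hybridised to 1 array each, per the labels' protocols. The authors deposited 1 value table with 53617 probes and 6 columns on the log2 scale; RMA and Partek 6.6 are named in the submitters' processing notes, without their order or role. The log2 unit was read from the range of the table, which runs from 2.41 to 14.22. The table holds no detection calls and no scan dates, so neither signal over background nor scan batches could be examined. No values were renormalised for the main comparison.

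Probes were named through the platform annotation given with the series. It pairs 16098 probes with 1 gene symbol each, none with several, and the other 37519 probes are unnamed here. The named probes cover 14884 genes. For the 779 genes with more than 1 probe, the probe with the highest mean over all 6 arrays was taken. Where probes of a named gene gave different values, this is said beside it.

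FAC-treated and untreated cells were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, 2-sided), with Benjamini-Hochberg adjustment over all 14884 genes and a threshold of 0.05. A count of changes of at least 1.5-fold was taken with the same threshold. The median SE of a log2 fold change was 0.07. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 27 lists, each with at least 5 measured genes. Adjusted p-values with a correlation estimated from the residuals are given beside every list that passed. The 27 lists held 605 genes, of which 372 had a named probe. They cover iron uptake, iron storage, export and heme breakdown, iron sensing and hepcidin control, heme synthesis and iron-sulfur clusters, complement, TGF-beta ligands, receptors and SMADs, TGF-beta induced targets, extracellular matrix and mesenchymal genes, NRF2 targets, antioxidant enzymes, metallothioneins, ferroptosis and lipid peroxidation, and HIF targets. The others cover NF-kappaB and inflammatory cytokines, interferon-stimulated genes, endoplasmic reticulum stress and ATF4 targets, heat shock genes, immediate early and ERK feedback genes, cholesterol synthesis, lysosome, cell cycle, p53 targets, retinal pigment epithelium, mitochondrial respiration, ribosomal proteins, blood and endothelial cell markers, and neuron, glia and photoreceptor markers. Some genes stand in more than 1 list.

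The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is at or above the median over all tested genes, leaving out uncharacterised loci and small RNA genes (17 of the 469 genes that met the other conditions). From each list it takes up to 4 members past the threshold with the largest changes or, where none passes, the 1 or 2 with the smallest p. It always takes a fixed set of genes of iron handling, complement and TGF-beta signalling, among them HMOX1, C3, CFB and SMAD3, and TFRC, FTH1, FTL, SLC40A1, TGFB1, TGFB2 and CEBPD, which have no named probe. This set was chosen knowing the study's subject, complement C3 and TGF-beta signalling in iron-loaded retinal pigment epithelium. Results for these genes are therefore not blind predictions. Genes named outside this rule are in the closing observations or are overlapping neighbours, and were chosen after their values were seen.

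The alternatives were leaving out the third of genes with the lowest mean, quantile normalization between arrays, centring each array on its median, a variance prior with an intensity trend and robust estimation, array weights, averaging all probes of a gene, testing every probe of the table, the replicate number as a block, and leaving out each array in turn. For lists, an estimated correlation, fry in place of camera, and ranks of the statistics were added. The procedure was tested on simulated data in 20 runs with 200 changed genes among 14884. It recovered 78.2% of genes changed by 0.5 on the log2 scale, 97.8% of those changed by 1 and 99.3% of those changed by 1.5, and 4.50% of its calls were false. The simulated noise was normal and independent, with variances drawn from limma's own fitted prior. These shares therefore hold only for data that follow that model. Changes below 0.5 were not simulated, though called genes such as C4A (0.31) and IDI1 (0.38) changed by less. With the HIF list shifted by -0.3 and genes drawn independently, camera called that list in 20 of 20 runs and called 0 of 520 other lists. Genes of a real list can correlate, so this does not give the rate of false list calls in these data. Reference positions of overlapping and neighbouring genes came from the RefSeq gene table, used only to see which genes adjoin each other.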

Results

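Gene expression was measured with arrays in ARPE-19 cells, an established human line of retinal pigment epithelium. The cells had been grown to confluence and kept at low serum to differentiate. They then spent 2 days in medium without serum, either with vehicle or with 250 µM FAC, in iron research the usual abbreviation of ferric ammonium citrate. Each group held 3 biological replicates on 6 arrays in all. The median log2 intensity over all probes lay between 6.03 and 6.09 on the 6 arrays, and pairs of arrays correlated over all probes with Pearson's r between 0.991 and 0.995. Levels below are mean log2 intensities ± SD (n = 3 per group), and changes are log2 fold changes of FAC over untreated ± SE, with limma's adjusted p.

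The comparison of FAC with vehicle asks which genes respond to FAC in this cell type. In the FAC-treated cells the central complement component C3 was 2.18-fold higher. Of the genes measured, 9 of 17 of cholesterol synthesis and 16 of 27 of the cell cycle rose, and 9 of 16 targets of hypoxia-inducible factors and 8 of 13 of TGF-beta fell. As lists these passed with a preset correlation between genes but not with an estimated one (in the same order, adjusted p = 0.106, 0.221, 0.129 and 0.106 with an estimated correlation). Among the genes that the naming rule admits, which leaves out uncharacterised loci, small RNA genes and genes of low level, the largest rises were those of LRIG1, a brake on receptor tyrosine kinases (1.43 ± 0.10, 2.69-fold, adjusted p = 0.000922), and BMP2, a secreted ligand of the bone morphogenetic protein family (1.29 ± 0.09, 2.44-fold, adjusted p = 0.000992). The largest falls under the same rule were those of CDK15 (-0.99 ± 0.10, adjusted p = 0.00385) and HMCN1, an extracellular matrix protein (-0.97 ± 0.12, adjusted p = 0.00803). Of 14884 genes tested, 555 changed at an adjusted p under 0.05, 280 higher and 275 lower with FAC. The change was at least 1.5-fold in 103 genes, of which 50 rose and 53 fell, and at least 2-fold in 12 genes, of which 10 rose and 2 fell. At an unadjusted p under 0.05 there were 2560 genes, and in 23.4% of genes the 3 values of 1 group all lay above the 3 of the other, where chance gives 10%. The count of 555 became 840 without the dimmest genes and 1026 with a variance prior that follows intensity. Without any 1 array it lay between 147 and 250, except for 447 without untreated replicate 2, and the 103 genes became 67 without untreated replicate 3.

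**Figure D1:**
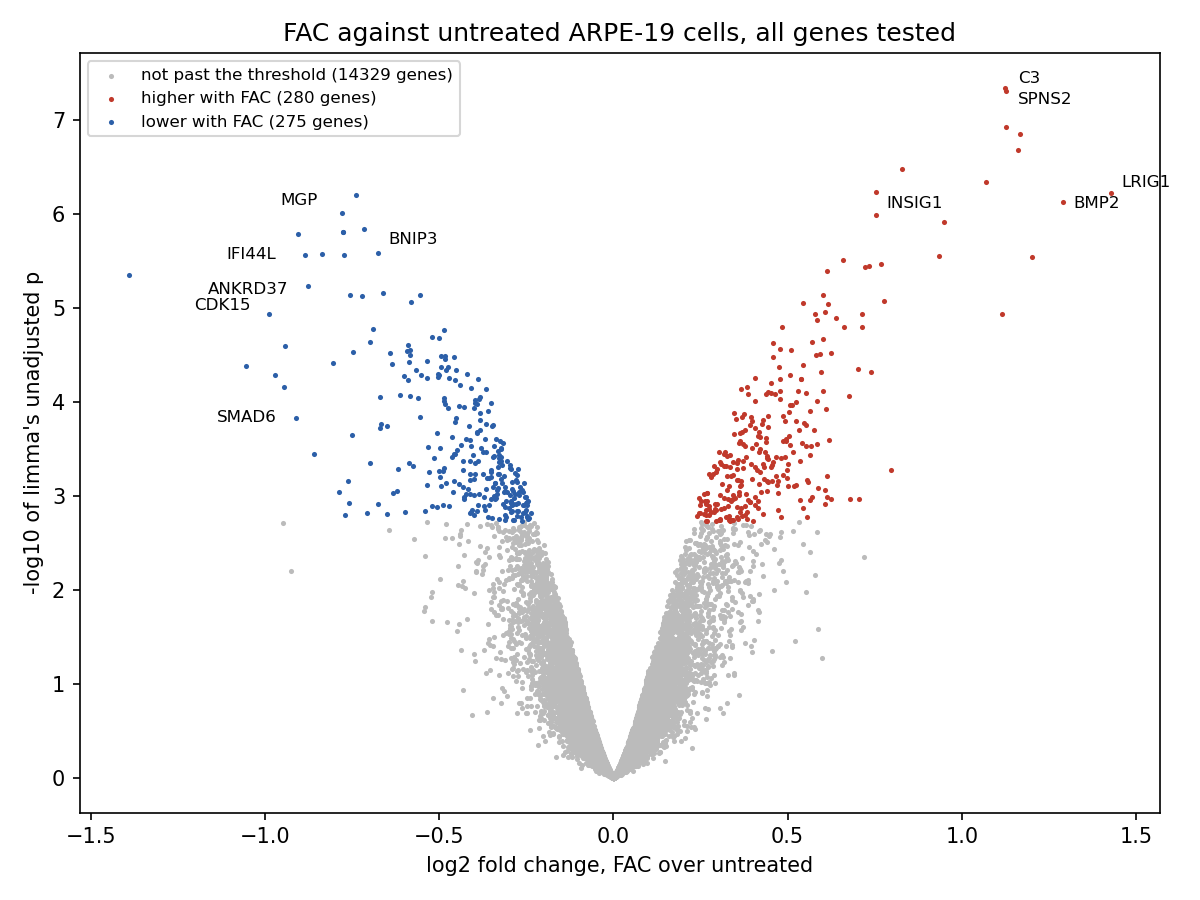
Each point is 1 of 14884 genes, with the log2 fold change of FAC over untreated on the x axis and -log10 of limma's unadjusted p on the y axis. Red marks the 280 genes that rose and blue the 275 that fell at an adjusted p under 0.05; C3 and SPNS2 stand at the top right.

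After LRIG1 and BMP2, the largest rises that the naming rule admits were those of CD180, a relative of the Toll-like receptors (1.20 ± 0.10), OLFML2A (1.17 ± 0.07), the long RNA SBF2-AS1 (1.16 ± 0.07), ASIC1, an acid-sensing ion channel (1.13 ± 0.06), C3, and SPNS2, an exporter of sphingosine-1-phosphate (1.13 ± 0.06). They were followed by the lysosomal protease gene CTSV (1.11 ± 0.12), TTC9 (1.07 ± 0.07), the Wnt inhibitor gene APCDD1 (0.95 ± 0.07) and PMAIP1, which encodes a pro-apoptotic BH3-only protein (0.78 ± 0.08). After CDK15 and HMCN1, the largest falls under this rule were those of LRRC32, whose product holds latent TGF-beta at the cell surface (-0.95 ± 0.13), the semaphorin receptor gene PLXNA4 (-0.94 ± 0.11), SMAD6, an inhibitor of BMP signalling (-0.91 ± 0.13), and the interferon-induced gene IFI44L (-0.88 ± 0.08). ANKRD37 (-0.88 ± 0.08), the phosphodiesterase gene PDE11A (-0.84 ± 0.07), the deubiquitinase gene USP35 (-0.81 ± 0.10), the pseudogene transcript RPSAP52 (-0.79 ± 0.15), MGP, an inhibitor of calcification (-0.78 ± 0.06), and MIR210HG, the host transcript of a hypoxia-induced microRNA (-0.78 ± 0.06), came next. RPSAP52 resembles its parent gene and overlaps HMGA2, so its value is uncertain, and SBF2-AS1 overlaps SBF2, which measured -0.14 ± 0.06 (adjusted p = 0.246).

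The complement genes show whether C3, part of the study's known subject, was higher with FAC. C3 rose from 6.91 ± 0.05 to 8.04 ± 0.06 (1.13 ± 0.06, adjusted p = 0.000362), and all 3 FAC arrays lay above all 3 untreated ones. C4A (0.31 ± 0.05, adjusted p = 0.0242) and C4B (0.28 ± 0.05, adjusted p = 0.0282), near-identical genes that arrays cannot fully separate, rose too. The alternative pathway gene CFB measured 6.69 ± 0.10 and 6.62 ± 0.16 (-0.07 ± 0.09, adjusted p = 0.738). In all, 3 of 17 measured complement genes rose, 4 adjusted over the list alone, and none fell. The list as a whole shifted upward by limma's camera test (adjusted p = 0.0474, and adjusted p = 0.221 with an estimated correlation), with a mean of 0.12 but a median of 0.02. That call was lost without untreated replicate 1 (adjusted p = 0.0577), untreated replicate 2 (0.0985), FAC replicate 1 (0.0743) or FAC replicate 3 (0.133), and with ranks of the statistics (0.285).

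**Figure D2:**
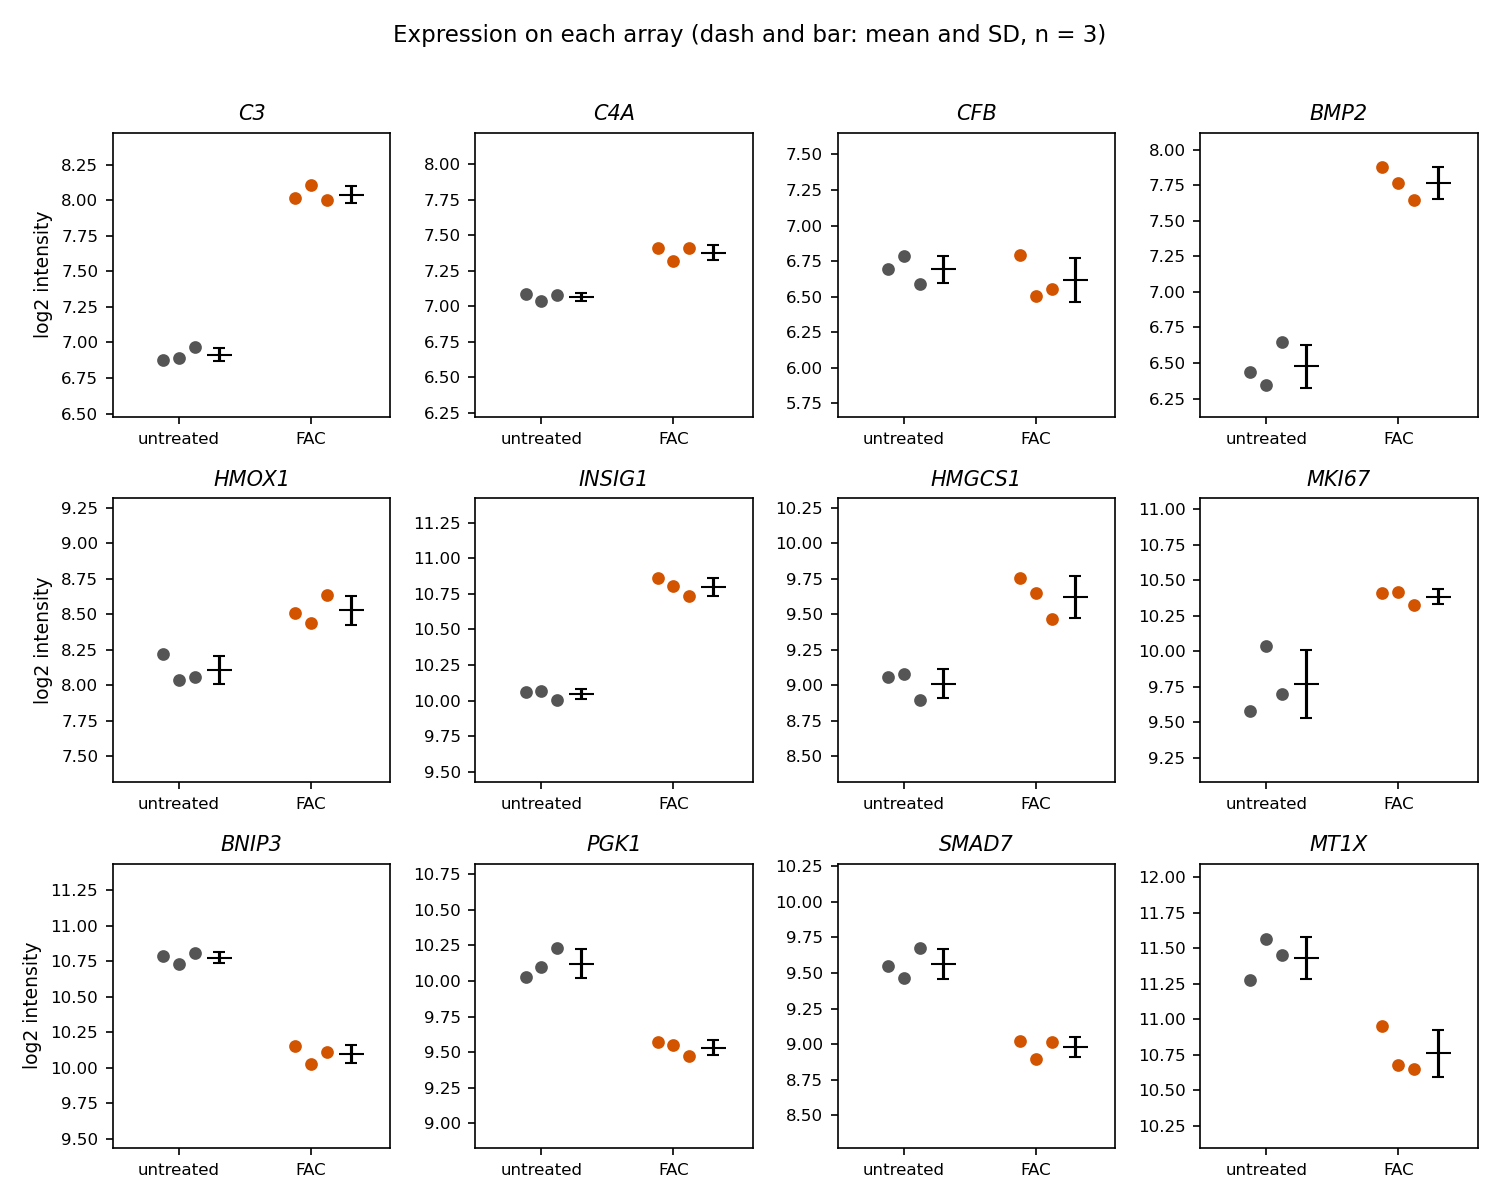
Log2 intensity of 12 genes on each of the 6 arrays, with grey points for untreated and orange points for FAC-treated cells; the dash and bar beside them are the mean and SD (n = 3), and every panel spans the same range. C3 rose from 6.91 to 8.04, BNIP3 fell from 10.77 to 10.10, and the values of CFB overlapped between the groups.

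Few of the measured genes of iron handling passed the test, apart from regulators of the BMP and hepcidin pathway. HMOX1, the heme-degrading enzyme, rose from 8.11 ± 0.10 to 8.53 ± 0.10 (0.42 ± 0.08, 1.34-fold, adjusted p = 0.0265) and was the 1 gene that rose among 11 measured genes of iron storage, export and heme breakdown, also when adjusted over the list alone. None of 6 measured iron uptake genes passed the test on either adjustment, over all genes or over the list alone. The ferric reductase gene CYBRD1 (0.09 ± 0.05, adjusted p = 0.443) and STEAP1 (-0.15 ± 0.13, adjusted p = 0.622) had the smallest p-values among the uptake genes. STEAP1 measured only 3.47 ± 0.24 in untreated and 3.31 ± 0.18 in FAC-treated cells, at percentile 1.6 of the tested genes by mean level. By this level, 50% of the 6 uptake genes lay among the dimmest 33.3% of tested genes. None of 17 measured genes of heme synthesis and iron-sulfur clusters passed on either adjustment, and ALAD (-0.20 ± 0.06, adjusted p = 0.137) and CPOX (-0.20 ± 0.07, adjusted p = 0.202) came closest. Among 10 measured genes of iron sensing and hepcidin control, BMP2 rose, while SMAD9 (-0.61 ± 0.08), the iron-induced ligand gene BMP6 (-0.42 ± 0.08) and HFE (-0.27 ± 0.06) fell; adjusted over the list alone, 4 rose and 4 fell. These 4 lists did not shift as wholes by camera (adjusted p = 0.895 for uptake and for storage, 0.910 for heme and clusters, 1.000 for sensing). Median, mean and test differed in sign in 3 of them. The median was 0.0067 and the mean -0.011 for uptake, with the test upward. Storage had a median of -0.0041 and a mean of 0.0042, with the test upward, and sensing had a median of 0.02 and a mean of 0.04, with the test downward. TFRC, FTH1, FTL and SLC40A1, the genes of the transferrin receptor, ferritin and ferroportin, were not analysed here for want of a named probe.

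Of 13 measured genes that TGF-beta induces, 8 fell. SMAD7, the feedback inhibitor of the pathway (-0.59 ± 0.07, adjusted p = 0.00714), ANGPTL4 (-0.58 ± 0.08, adjusted p = 0.0101), the NADPH oxidase gene NOX4 (-0.58 ± 0.06, adjusted p = 0.00334) and LTBP2 (-0.53 ± 0.06, adjusted p = 0.00714) fell the most, and a second probe of LTBP2 gave -0.34. None of the targets rose, and adjusted over the list alone 11 fell. The list's median was -0.40 (camera adjusted p = 1.75e-11, and adjusted p = 0.106 with an estimated correlation). Among 16 measured genes of the list of TGF-beta ligands, receptors and SMADs, the inhibitors SMAD6 and SMAD7 and the latent TGF-beta binding protein gene LTBP2 fell and none rose. Adjusted over the list alone, 7 fell and 1 rose, the BMP antagonist gene NOG. The 16 hold no gene of TGF-beta itself and neither TGFBR1 nor TGFBR2, and SMAD7 and LTBP2 are also among the 13 targets above. The signal transducer SMAD3 measured 7.39 ± 0.06 and 7.28 ± 0.04 (-0.10 ± 0.06, adjusted p = 0.394). This list's median was -0.09 (camera adjusted p = 0.0126, and adjusted p = 0.177 with an estimated correlation), and it did not pass with ranks of the statistics (adjusted p = 0.128). TGFB1 and TGFB2 were not analysed here, having no named probe. Among 15 measured extracellular matrix and mesenchymal genes, FBLN5 rose (0.53 ± 0.08), and LUM (-0.56 ± 0.08) and the collagen cross-linking enzyme gene LOX (-0.26 ± 0.05) fell; adjusted over the list alone, 1 rose and 5 fell. That list did not pass (camera adjusted p = 0.0571).

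Of 16 measured genes induced by hypoxia-inducible factors (HIF), 9 fell. ANKRD37 fell by 0.88 on the log2 scale (1.84-fold lower, adjusted p = 0.00278). The mitophagy gene BNIP3 fell from 10.77 ± 0.04 to 10.10 ± 0.07 (-0.68 ± 0.06, adjusted p = 0.00178). The glycolytic genes HK2 (-0.59 ± 0.07, adjusted p = 0.00662) and PGK1 (-0.59 ± 0.07, adjusted p = 0.00617) fell as well. Adjusted over the list alone 11 of the HIF targets fell, and none rose on either adjustment. The median was -0.34 (camera adjusted p = 7.71e-13, and adjusted p = 0.129 with an estimated correlation).

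Of 17 measured genes of cholesterol synthesis, 9 rose. INSIG1, a sterol-responsive regulator of the pathway, rose from 10.05 ± 0.03 to 10.80 ± 0.06 (0.75 ± 0.06, 1.69-fold, adjusted p = 0.00115). The enzyme genes HMGCS1 (0.61 ± 0.09, adjusted p = 0.0118), ACAT2 (0.44 ± 0.06, adjusted p = 0.01) and IDI1 (0.38 ± 0.05, adjusted p = 0.00929) followed. Adjusted over the list alone 14 of these genes rose, and none fell on either adjustment, with a median of 0.33 (camera adjusted p = 3.57e-13, and adjusted p = 0.106 with an estimated correlation).

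Of 27 measured cell cycle genes, 16 rose. The mitotic checkpoint kinase gene BUB1 (0.68 ± 0.14, adjusted p = 0.0373), the proliferation marker MKI67 (0.61 ± 0.11, adjusted p = 0.0277), the mitotic kinesin gene KIF20A (0.58 ± 0.06, adjusted p = 0.00385) and CDC20 (0.57 ± 0.11, adjusted p = 0.0365) rose the most. Of 13 alternatives read for single genes, BUB1 did not pass in 6, MKI67 in 5 and CDC20 in 5, while KIF20A passed in all. Adjusted over the list alone 27 rose, and none fell on either adjustment. The median was 0.36 (camera adjusted p = 8.52e-22, and adjusted p = 0.221 with an estimated correlation). The estimated correlation between these genes was 0.622, the highest of the 27 lists. Untreated replicate 2 stood apart from the other untreated arrays over this list, with a mean deviation of -0.04 against -0.31 and -0.23 for untreated replicates 1 and 3, and 0.23, 0.20 and 0.16 for the FAC arrays.

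**Figure D3:**
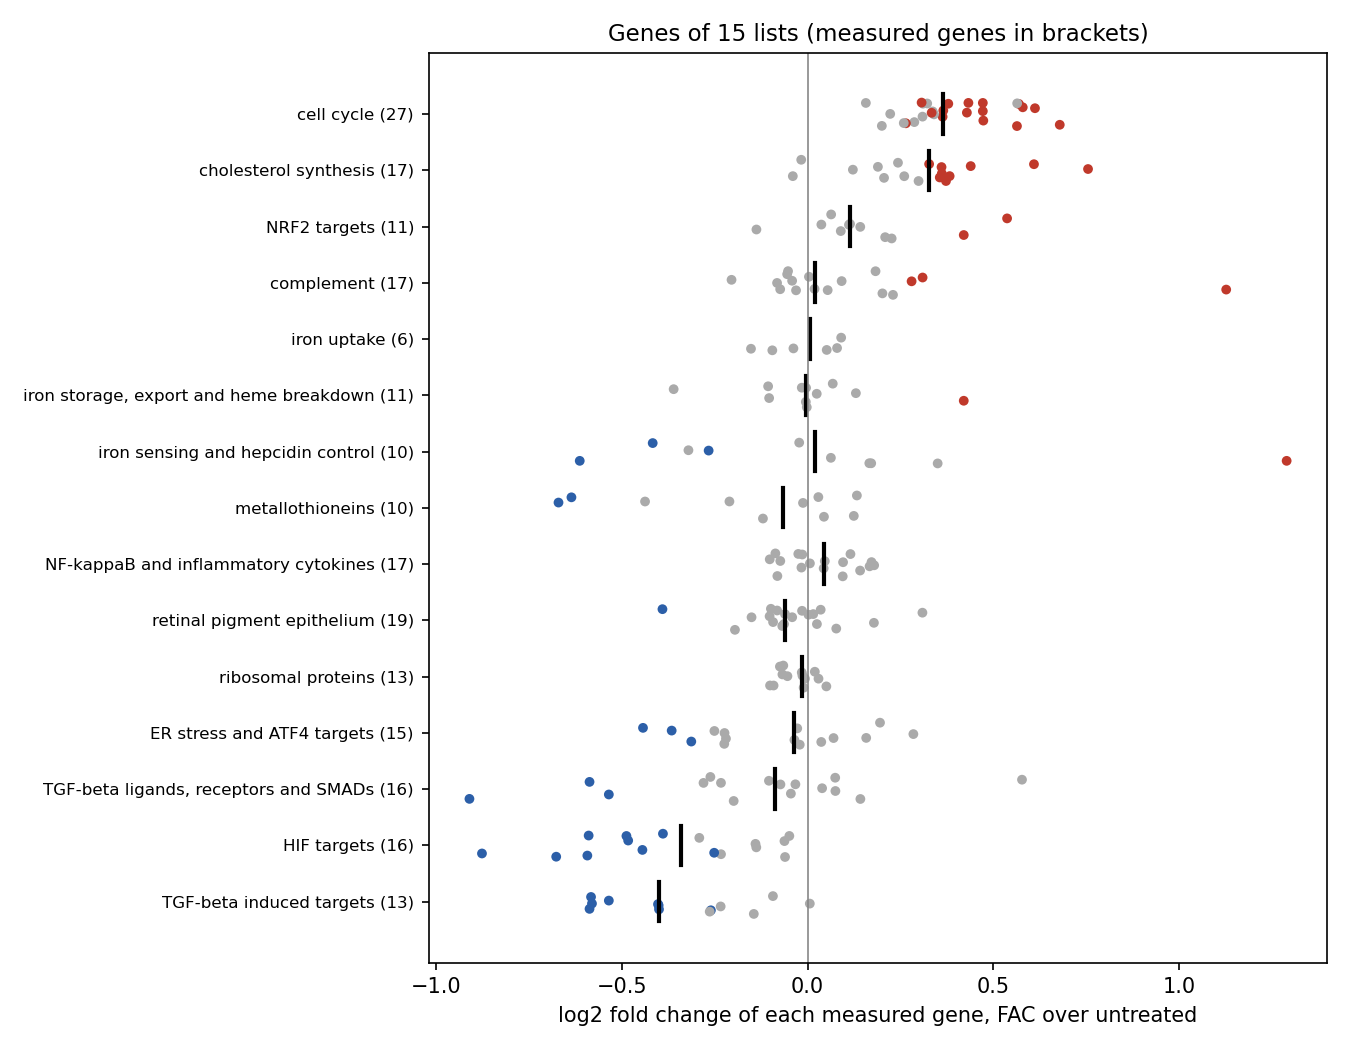
Log2 fold change of each measured gene in 15 of the 27 lists, FAC over untreated, with the number of measured genes in brackets. Red and blue points rose or fell at an adjusted p under 0.05 over all genes, grey points did not pass, and black bars are medians, which run from 0.36 for the cell cycle to -0.40 for TGF-beta induced targets.

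Of 11 measured NRF2 targets, the pentose phosphate enzyme gene TKT (0.54 ± 0.07, adjusted p = 0.00804) and HMOX1 rose, 4 genes rose when adjusted over the list alone, and none fell. The median was 0.11 (camera adjusted p = 0.000790, and adjusted p = 0.129 with an estimated correlation). Among 10 measured metallothionein genes and their regulators, MT1X (-0.67 ± 0.10) and MT1F (-0.64 ± 0.08) fell, 3 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0778). Metallothioneins are closely similar in sequence, so their separate values are uncertain. The peroxiredoxin gene PRDX4 fell (-0.36 ± 0.07) as the 1 gene among 19 measured antioxidant enzymes on either adjustment (camera adjusted p = 0.895). Among 12 measured genes of ferroptosis and lipid peroxidation, the arachidonate lipoxygenase gene ALOX5 rose (0.59 ± 0.06) and no other passed on either adjustment (camera adjusted p = 0.417).

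Among 15 measured genes of endoplasmic reticulum stress and ATF4, VLDLR (-0.44 ± 0.06), the secreted chaperone-like factor gene MANF (-0.37 ± 0.05) and XBP1, a transcription factor of the unfolded protein response (-0.31 ± 0.06), fell. Adjusted over the list alone, 7 fell and 1 rose, and the median was -0.04 (camera adjusted p = 0.0281, and adjusted p = 0.440 with an estimated correlation). Without untreated replicate 3 (adjusted p = 0.0624) or FAC replicate 2 (adjusted p = 0.0688) that list no longer passed, nor with ranks of the statistics (adjusted p = 0.243). None of 8 measured heat shock genes passed on either adjustment, and HSPH1 (0.15 ± 0.06, adjusted p = 0.246) and BAG3 (-0.11 ± 0.07, adjusted p = 0.457) had the smallest p-values (camera adjusted p = 0.910). PMAIP1 was the 1 gene that rose among 11 measured p53 targets on either adjustment (camera adjusted p = 0.199).

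None of 17 measured NF-kappaB and cytokine genes passed on either adjustment, with NFKB1 at 0.17 ± 0.06 (adjusted p = 0.160) and CXCL8 at 0.14 ± 0.06 (adjusted p = 0.251), and the list did not pass (camera adjusted p = 0.429). Of these 17 genes, 52.9% lay among the dimmest 33.3% of tested genes by mean level. CXCL8 measured only 4.36 ± 0.05 in untreated and 4.50 ± 0.06 in FAC-treated cells, at percentile 8.0. Without detection calls a response of such dim genes could be missed, so an inflammatory response is not excluded. Among 20 measured interferon-stimulated genes IFIT3 rose (0.49 ± 0.07) and IFI44L fell, while 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.246). Of 19 measured immediate early and ERK feedback genes, the feedback inhibitor gene SPRY2 rose (0.50 ± 0.09), and MYC (-0.46 ± 0.08), EGR1 (-0.43 ± 0.06) and IER3 (-0.30 ± 0.06) fell, the same counts as adjusted over the list alone (camera adjusted p = 0.8). A second probe of EGR1 gave -0.02 and other probes of IER3 gave between -0.32 and -0.05, and neither gene passed when its probes were averaged (adjusted p = 0.108 and 0.138).

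Few housekeeping and identity genes passed the test. Among 19 measured genes of retinal pigment epithelium, the retinol dehydrogenase gene RDH10 fell (-0.39 ± 0.08), and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.535). Over this list untreated replicate 2 lay lowest, with a mean deviation of -0.08 against 0.09 and 0.05 for untreated replicates 1 and 3. The lysosomal protease gene CTSK rose (0.36 ± 0.06) as the 1 gene of 16 measured lysosomal genes on either adjustment (camera adjusted p = 0.826). None of 7 measured mitochondrial respiration genes passed on either adjustment, with COX5A at 0.14 ± 0.07 (adjusted p = 0.390) and CYC1 at -0.06 ± 0.05 (adjusted p = 0.622), and the list did not pass (camera adjusted p = 0.895). None of 13 measured ribosomal protein genes passed on either adjustment, with RPL10A at -0.10 ± 0.06 (adjusted p = 0.466) and RPS6 at -0.09 ± 0.06 (adjusted p = 0.475), and the list did not pass (camera adjusted p = 0.530). Of 8 measured markers of blood and endothelial cells, CSF1R fell (-0.37 ± 0.07) on either adjustment (camera adjusted p = 0.895, with a median of 0.02, a mean of -0.05 and a downward test). By mean level, 75% of these 8 markers lay among the dimmest 33.3% of tested genes, where a change could be missed. None of 7 measured markers of neurons, glia and photoreceptors passed on either adjustment, with SAG at 0.27 ± 0.08 (adjusted p = 0.118) and SYT1 at -0.21 ± 0.07 (adjusted p = 0.174), and the list did not pass (camera adjusted p = 0.246). For these 7 markers the share among the dimmest 33.3% of tested genes was 42.9%.

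None of the list calls passed with an estimated correlation, and the number of arrays limits the precision of every value. The vehicle control does not separate iron from the other ions that FAC brings.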

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

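The tests on intensity, on single arrays, on genes shared with hypoxia and on growth were chosen after the result was seen. The second gene lists and the splits of the arrays were set down before their values were looked at.

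Probes that carry no gene name here also responded: of 37519 such probes, 142 changed at an adjusted p under 0.05 in a limma fit over all probes of the table, 51 higher and 91 lower with FAC. At least 1.5-fold changes made up 86 of them, and log2 fold changes of unnamed probes reached from -2.12 to 1.97. They drew attention as a signal in data that the comparison of named genes does not use.

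The fall of HIF targets has a median of -0.34, below the medians of all 10000 random lists of equal size matched on mean expression, which argues against a shift that depends on intensity. Without any 1 array the list's mean stayed at -0.333 or lower, against an effect of 1 array. A second list of 16 other measured HIF targets had a median of -0.261, below all 10000 matched lists, and 9 of its genes fell, among them RORA (-0.65 ± 0.10) and PGM1 (-0.48 ± 0.06). With an estimated correlation camera's unadjusted p was 0.0208 for this list. For the first list it was 0.0191, which became 0.129 when adjusted. The p-values of the second lists were not adjusted for their number. Genes of both HIF lists correlate (estimates of 0.230 and 0.179), which random lists ignore. A candidate explanation is lower HIF activity in the FAC-treated cells, since iron is a cofactor of the prolyl hydroxylases that mark HIF for degradation. HIF protein was not measured, and the other ions that FAC brings stay open as untested.

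The rise of cell cycle genes has a median of 0.364, above all 10000 matched random lists, and its mean stayed at 0.334 or higher without any 1 array. A second list of 20 other measured cell cycle genes had a median of 0.386, above all 10000 matched lists, and 7 of its genes rose, led by NUSAP1 (0.70 ± 0.09). Its genes correlate strongly, which random lists ignore, and camera gave an unadjusted p of 0.0595 with an estimated correlation, so the list does not pass by that test. Cultures that differ in growth apart from FAC may also give this, and the set tests that allow for correlated genes differ: for the first list camera with an estimated correlation gave an adjusted p of 0.221 and fry one of 0.0167, so this explanation stays open.

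The fall of TGF-beta induced targets has a median of -0.40, below all 10000 matched random lists, and its mean stayed at -0.32 or lower without any 1 array. Without ANGPTL4 and NOX4, the measured members picked as also induced by hypoxia, the other 11 genes had a mean of -0.301 ± 0.055. That SE is over genes and treats them as independent. The fall thus does not rest on ANGPTL4 and NOX4 alone. Whether others of the 11 genes also respond to hypoxia was not examined, so a part of the HIF response in this fall stays open. A second list of 10 other measured TGF-beta targets was less clear. Its median of -0.125 lay at percentile 0.38 of matched lists and SPHK1 and TNS1 fell, but 3 members measured higher and camera gave an unadjusted p of 0.113, or 0.173 with an estimated correlation. Lower TGF-beta signalling in the FAC-treated cells may account for the first list and is a hypothesis that was not tested. TGFB1 and TGFB2 were not analysed here.

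There are 10 ways to split the 6 arrays into 3 and 3, too few for a share under 0.05. For the 555 changed genes, 1 split reached that count, the real one, and the highest of the others was 0. For the 103 genes changed at least 1.5-fold it was also 1 split, with 0 as the highest of the others, and for the 8 lists 1 split, with 5 as the highest of the others.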

How the results depend on the processing

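The 555 changed genes became 840 without the dimmest 33.3% of genes, 1026 with an intensity trend and robust variance prior, 254 probes with every probe of the table, and 184 with the replicate block. Same-numbered arrays deviated from their group means with correlations of -0.02, -0.03 and -0.15, and none was closest to its own number. No pairing by number was thus visible, and the cultures were treated as unpaired. Whether same-numbered cultures were run side by side is not stated, so the count with the replicate block cannot be set aside. Leaving out 1 array gave between 147 and 447 genes: 250 without untreated replicate 1, 447 without untreated replicate 2, 150 without untreated replicate 3, 147 without FAC replicate 1, 203 without FAC replicate 2 and 215 without FAC replicate 3, where a group then held 2 arrays. Changes of at least 1.5-fold numbered between 67 (without untreated replicate 3) and 122 (without untreated replicate 2), against 103 with all. With an estimated correlation 0 lists passed (8 with the preset one), and with ranks of the statistics 5 passed; the cause was not tested. With fry 11 lists passed, and with the replicate block 6, without complement and ER stress (adjusted p = 0.0757 for both). The remaining alternatives kept the count of genes between 550 and 626, and the balance of calls turned from 280 higher and 275 lower to 254 higher and 316 lower (44.6% against 50.5% higher) after centring each array on its median. At 1.5-fold it turned from 50 higher and 53 lower to 55 and 46 with quantile normalization. Of 64 named genes past the threshold, 33 passed under every alternative except the fit over every probe, which was not read for single genes. Leaving out an array set aside as well, 43 did, and 0 changed sign under these alternatives. C3, BMP2, INSIG1, BNIP3 and SMAD7 were among the 33, while HMOX1 (adjusted p between 0.00353 and 0.104) and C4A (between 0.00876 and 0.108) were not. Of the cell cycle genes named, KIF20A was among them. BUB1 (adjusted p between 0.00407 and 0.147), MKI67 (between 0.00203 and 0.119) and CDC20 (between 0.00361 and 0.127) were not. The complement call was also lost with quantile normalization (adjusted p = 0.08) and with array weights (adjusted p = 0.0589). The table holds no detection calls, so what signal over background limits is unknown.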

Other observations

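The genes of this and the next paragraph were chosen after their values were seen, and the test of BMP targets after part of its values was. The genes of these paragraphs were not tested as sets. Of 17 measured genes of fatty acid and lipid synthesis, 8 rose with FAC, 9 did not pass and none fell. SREBF1, the gene of the transcription factor SREBP1, rose by 0.41 ± 0.07 (log2 fold change ± SE, n = 3 per group), FASN, the fatty acid synthase gene, by 0.41 ± 0.05, the desaturase gene FADS1 by 0.43 ± 0.06, the acyl-CoA synthetase gene ACSL1 by 0.51 ± 0.07 and LPIN1 by 0.39 ± 0.06. Among those that did not pass, SCD measured 0.28 ± 0.06 (adjusted p = 0.0557). Of 13 measured genes that help collagen and other secreted proteins fold, move or stay in the endoplasmic reticulum, 8 fell, 5 did not pass and none rose. The collagen hydroxylase gene P3H1 fell (-0.38 ± 0.05), as did FKBP7 (-0.50 ± 0.06), PPIC (-0.41 ± 0.07), PPIB (-0.25 ± 0.05), KDELR3 (-0.45 ± 0.06) and HYOU1 (-0.31 ± 0.06).

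Of 1072 measured microRNA genes, 7 rose, led by MIR4668 (0.80 ± 0.14), MIR4655 (0.61 ± 0.12) and MIR15B (0.61 ± 0.12), 19 fell and 1046 did not pass. Of all 14884 genes tested, 280 rose and 275 fell. No minimum level was asked of the microRNA genes, and whether their values reflect mature microRNAs was not examined. Some of those that fell lie beside each other or within a host transcript that fell. MIR31 fell by 0.62 on the log2 scale and its host MIR31HG by 0.43. The adjoining genes MIR221 (-0.42 ± 0.05) and MIR222 (-0.37 ± 0.08) fell, as did MIR216A (-0.86 ± 0.15) and MIR217 (-0.75 ± 0.12). RPSAP52 (-0.79 ± 0.15) and HMGA2 (-0.68 ± 0.14), which overlap, also fell. The largest fall of all named genes was that of the uncharacterised C5orf46 (-1.39 ± 0.13, 2.62-fold lower, adjusted p = 0.00222), which the naming rule leaves out.

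BMP2 (1.29 ± 0.09), BMP4 (0.66 ± 0.07) and the related ligand gene GDF5 (0.73 ± 0.06) rose, while BMP6 (-0.42 ± 0.08) fell, and a list of BMP-SMAD targets tested whether BMP signalling in the cells may have risen with the 3 ligands that rose. Of its 21 genes, SMAD6, SMAD7, SMAD9, NOG and BAMBI also stand in the fixed lists, so their values had already been computed. The 19 measured BMP-SMAD targets had a median of -0.00563, at percentile 37.5 of matched random lists. None of them rose, and SMAD6, SMAD7 and SMAD9, which the signal induces, fell, while NOG measured 0.58 ± 0.16 (adjusted p = 0.104). The median gave no sign of higher BMP signalling on the second day. Given the spread of these genes it does not exclude it. Several of them also measured low, such as HEY1 (5.77 in untreated and 5.67 in FAC-treated cells) and SMOC2 (5.65 and 5.79). Others did not, such as CHRDL1 (10.79 and 10.69), and the median over all tested genes was 7.18. If the low targets are little expressed, the list's median could hardly move, so the question stays open. All 3 fallers are among the genes whose values had been computed, and SMAD7 is also a TGF-beta target.

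BMAL1, a core gene of the circadian clock, fell by 0.72 on the log2 scale (1.64-fold lower, adjusted p = 0.00133). The test assumed that with a shifted clock, genes opposite to it in phase, listed before their values were looked at, would rise. All arrays were from day 2, and a shift need not raise every such gene at that time. The 7 measured ones had a median of 0.0464, at percentile 87.2 of matched random lists, and none passed the test, from PER3 at 0.15 ± 0.06 down to HLF at -0.10 ± 0.13. The bound set for the list was not passed, but the median lies below it by less than the spread of so few genes, so a shift of the clock was neither shown nor excluded and may still play a part. For the clock and BMP lists, how the spread of the genes and the count of falling targets were weighed was settled after these values were seen.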
